A study of Homo sapiens with 10 samples.

How the data were processed

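RNA was measured by sequencing in cardiomyocytes differentiated from H9, an established human embryonic stem cell line, that carried a doxycycline-inducible CITED4 gene introduced by lentivirus. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the VAHTS Universal V6 kit. The labels gave 5 libraries of untreated cells (control) and 5 libraries of cells given doxycycline. They did not say whether the 5 libraries of a group came from separate cultures or differentiations, so p-values measure only the spread between these libraries, which may be technical. No dose, duration or day of differentiation was given in the sources used here, and doxycycline-treated cells without the transgene were not analysed here.

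The authors deposited FPKM values (fragments per kilobase of gene per 1000000 fragments, M below standing for 1000000) for 24724 gene symbols in 10 columns, 1 per library. Per the submitters' processing notes, the genome build was GRCh38.p13 and DESeq2 was among the authors' tools, with no role stated. The aligner, the counting program, its annotation and its use of strand are not given in the sources used here. Of the symbols, 23354 were found in a RefSeq table of assembly GRCh38.p14, which was used only for names and lengths. Coordinates, transcript length and GC content came from GENCODE 29 on GRCh38, and 95.8% of the tested genes had a GC value, taken from the longest transcript of the symbol.

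FPKM values are not counts, so no count model was used. The depth behind them was recovered from low values, which step in whole multiples of what 1 fragment is worth for a gene of given length. It was 39.3 to 39.7 M fragments per library in 9 of the 10 libraries and 35.2 M in control 2. Of 1766 genes above 0 in every library with at most 200 recovered fragments in each, 289 came out whole in all 10 libraries within a tolerance of 0.02, where chance would give 1.9e-11. Genes whose counted length differs from the length in the RefSeq table cannot come out whole. On those 289 genes, with at least 10 fragments over both libraries, the chi-square per gene between replicates of a group ran from 3.85 to 5.07 over 20 pairs, with a largest p of 1.28e-92, so no pair was a library deposited more than once. The lowest Pearson correlation across genes between replicates was 0.9959. At these depths an FPKM of 1 over 1 kb corresponds to 35.2 to 39.7 fragments.

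Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear fit on group, empirical Bayes with a variance trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) over 11962 genes with an FPKM of at least 1 in at least 5 libraries. Fold changes are on that scale, which understates the change of low genes. An exact permutation test over all groupings of 5 and 5 was used for single values (Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3), and 0.0079 is the smallest p it can give. Each 95% bootstrap interval of a list's median resampled the genes of the list, not the libraries. Such an interval holds no spread between libraries and takes the genes as independent. It is set beside 0, though the median log2 fold change of all tested genes was 0.022. For 33 gene lists, members that rose or fell past the threshold over all tested genes were counted, and also adjusted over the list alone. The 31 lists with at least 5 tested members were tested with camera against all other genes, with an inter-gene correlation preset at 0.01, and again with an estimated correlation. fry was run beside it to ask whether a list's genes moved on balance one way. The tests, the lists, most of the other settings tried and the rule for named genes were fixed before the data were examined. The named genes are CITED4, the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose groups did not overlap and whose mean FPKM was at least 2 in the higher group, up to 4 members with the smallest p of each list that passed camera or had at least 3 changed members, and 14 cardiac, growth and stress genes whatever their result. XIST, Y-linked genes and clone-style names were left out of these. Some genes that the rule selects are withheld and not reported. List members named outside the rule are marked as chosen after their values were seen.

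The gene and list tests were tested on simulated data with the real means and spreads of the 11962 genes, in 5 runs with 200 changed genes each. Of the genes changed by 0.3 on the log2 scale 72% were called, of those changed by 0.5 96.7% and of those changed by 1 99.7%, and 5.4% of the calls were false. The simulated genes were independent of each other, so the run on lists says nothing about correlated members.

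The other settings fixed in advance were a pseudocount of 0.1 or 5, no filter or a mean FPKM of at least 5, median scaling, TPM, quantile normalization and TPM without mitochondrial genes and CITED4, a fit with no variance trend or a robust one, array weights, the replicate number as a block, each library left out in turn, and the estimated correlation for lists. Added after the data were seen were a correction of each library for its trend on GC content (lowess, span 0.3), a correction for GC content and length, the library's GC slope as a covariate, the physiological growth list without CITED4, and a fit without the 3 libraries whose slope was above 0.05 log2 units per 10 points of GC.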

Results

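The transcriptome of H9-derived cardiomyocytes carrying an inducible CITED4 gene was measured in 10 libraries, 5 from control cells and 5 from cells given doxycycline, which switches the transgene on. CITED4 is a transcriptional cofactor that binds CBP and p300, and the study's title places it in a model of physiological growth of the heart muscle. The design holds 1 comparison, doxycycline against control, in which the drug and the induced gene always go together. Recovered depth was 39.6 ± 0.12 M fragments (M, 1000000; SD, n = 5) in doxycycline libraries and 38.6 ± 1.90 M (SD, n = 5) in control libraries, a difference within the spread (exact permutation p = 0.159, two-sided). Mitochondrially encoded transcripts made up 15.3% ± 0.30 (SD, n = 5) and 15.1% ± 0.43 (SD, n = 5) of summed FPKM (exact permutation p = 0.397). The 10 most abundant genes of each library made up 15.7% ± 0.13 and 15.3% ± 0.18 (SD, n = 5 each; exact permutation p = 0.016).

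CITED4 was 8.81-fold higher with doxycycline. Its level was 129.7 ± 11.1 FPKM (SD, n = 5) with doxycycline, from 116.7 to 143.9, and 14.7 ± 1.59 FPKM (SD, n = 5) in control cells, from 12.9 to 16.4. The rise was 3.06 on the log2 scale (SE 0.07, limma adjusted p = 1.85e-12) and was seen in each of the 5 doxycycline libraries against each control library, with an exact permutation p of 0.0079, the smallest the design can give. The gene lies on the minus strand of chromosome 1, from 40861051 to 40862366 on GRCh38 (GENCODE 29, ENSG00000179862.6), as 1 exon. Its values corresponded to 595 to 846 fragments in control libraries and 6059 to 7490 in doxycycline libraries. Reads of the transgene and of the cell's own gene are not told apart, and a transgene without the untranslated regions would be understated by an FPKM over the whole gene.

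**Figure D1:**
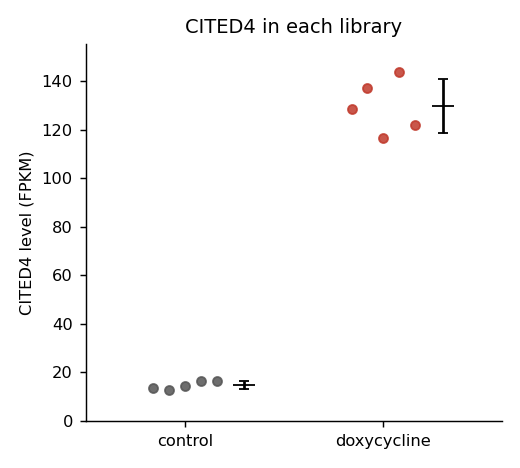
CITED4 level in FPKM (vertical axis) in each of the 5 control and 5 doxycycline libraries (points), with the mean and SD of each group beside them. The doxycycline libraries sit between 116.7 and 143.9 FPKM and the control libraries between 12.9 and 16.4.

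Across the transcriptome, changes were many and small. Of 11962 tested genes, 1133 passed the threshold, 531 higher and 602 lower with doxycycline. Among them 1056 changed by less than 0.5 on the log2 scale, and the median size was 0.26. The median log2 fold change of all tested genes was 0.022, not 0. Camera compares a list with the other genes, so a list with a median just above 0 can have the direction lower. On the log2(FPKM + 1) scale only CITED4, NPY and MHRT changed by 2-fold or more. This count depends on the pseudocount and scaling and lay between 1 and 8 over the alternatives run. NPY, a neuropeptide, fell by 1.22 on the log2 scale (SE 0.13, adjusted p = 3.96e-05), from 6.91 ± 1.48 to 2.39 ± 0.54 FPKM (SD, n = 5 each). MHRT, a noncoding RNA transcribed antisense to MYH7, fell by 1.04 (SE 0.12, adjusted p = 0.000107), and since the counting is not stated to use strand, its reads and those of MYH7 may not be separate. The groups did not overlap for 9.4% of the tested genes, where chance gives 0.79%. The count of changed genes was 639 with the replicate number as a block, 1700 after a correction for the libraries' GC trend and 747 without 3 GC-rich libraries.

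**Figure D2:**
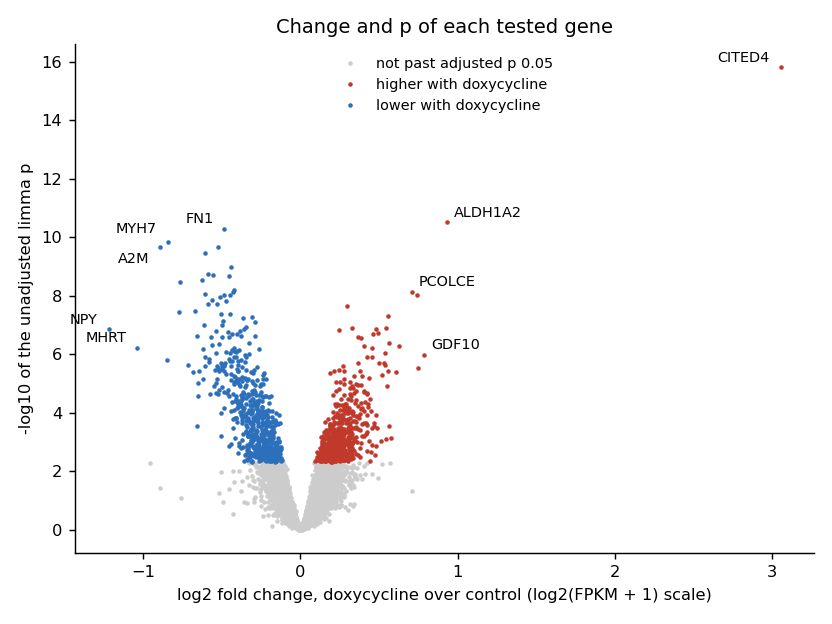
Each point is a tested gene, with its log2 fold change on the log2(FPKM + 1) scale (horizontal axis) and the -log10 of its unadjusted limma p (vertical axis). CITED4 stands apart at 3.06, and most of the 531 higher and 602 lower genes lie within 0.5 of no change.

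Among the reported genes that rose, ALDH1A2 had the largest log2 fold change after CITED4. This enzyme, which makes retinoic acid, went from 11.6 ± 0.74 to 23.1 ± 1.31 FPKM (SD, n = 5 each), a rise of 0.93 on the log2 scale (SE 0.05, adjusted p = 1.86e-07). GDF10, a secreted factor of the TGF-beta family, rose by 0.78, SERHL2 by 0.75, the glycosyltransferase GALNT16 by 0.74 and PCOLCE, an enhancer of procollagen processing, by 0.71. This order holds on the log2(FPKM + 1) scale. As ratios of mean FPKM, GALNT16 was at 2.333 and GDF10 at 2.013, against 1.985 for ALDH1A2. KRT4, PTGDS, SMIM1, MHENCR, the matrix protein FBLN2 and INMT rose by 0.56 to 0.63. The calls of SMIM1 and MHENCR ended with no filter on low values and without the 3 GC-rich libraries (limma adjusted p up to 0.0873 and 0.0547). Among reported genes past the threshold whose groups did not overlap, with a mean of at least 2 FPKM in the higher group, the largest falls next to NPY and MHRT were those of the protease inhibitor A2M (-0.89), the opioid precursor PENK (-0.85), MYH7 (-0.85), LYPD1 (-0.77), the metalloprotease PAPPA (-0.77), ACTA1 (-0.72), TGFBI (-0.67), GPR158 (-0.66), GADD45G (-0.65) and ACTG2 (-0.65). The rule that picked these 24 genes, CITED4 included, required groups that did not overlap, and their adjusted p was at most 0.0141. As a ratio of mean FPKM, GPR158 was at 0.457. Rises were most frequent among GC-rich genes: 229 of the 2292 genes in the upper GC range (58.5% to 74.5%) rose, against 14 of 2292 in the lower range (31.3% to 41.1%). After the GC correction 192 rose and 202 fell in the upper range, and 61 rose and 128 fell in the lower.

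Genes of the contractile apparatus fell. Of 28 tested sarcomere genes 14 fell and none rose past the threshold, and 18 fell and 1 rose adjusted over the list alone (camera adjusted p = 4.62e-16, and adjusted p = 0.0393 with an estimated correlation). MYH7, the slow beta-myosin heavy chain, went from 333.1 ± 26.4 to 184.6 ± 8.89 FPKM (SD, n = 5 each; adjusted p = 4.35e-07). The ventricular light chains MYL3 and MYL2 fell by 0.60 and 0.50 on the log2 scale, ACTC1, the cardiac alpha-actin, by 0.45, and CSRP3, a Z-disc protein, by 0.56. MYH6, the fast alpha-myosin heavy chain, was at 153.5 ± 12.98 FPKM in control and 175.0 ± 13.8 in doxycycline libraries (SD, n = 5 each), which did not pass (log2 fold change 0.19, adjusted p = 0.0689). TNNT2 (-0.12, adjusted p = 0.0529), TNNI1 (0.10) and TNNI3 (0.05) did not pass either. In the ventricular list 7 of 12 fell (9 adjusted over the list alone, camera adjusted p = 4.27e-10, and adjusted p = 0.0207 with an estimated correlation), FHL2 and the transcription factor IRX4 among them, by 0.32 and 0.29. In the atrial and nodal list 4 of 13 fell and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 1.95e-05, and adjusted p = 0.0393 with an estimated correlation). NPPA fell by 0.48, MYL4 by 0.31 and MYL7 by 0.23, while the pacemaker channel HCN4 rose by 0.24. Of 19 cardiac transcription factors only IRX4 fell past the threshold, with 8 lower adjusted over the list alone (camera adjusted p = 0.000508, and adjusted p = 0.0626 with an estimated correlation). The call of IRX4 ended with the replicate block (adjusted p = 0.0533) and without control 1, 3 or 4 or doxycycline 3 (adjusted p of 0.0543 to 0.0616). GATA6 (-0.14), HAND2 (-0.11) and ISL1 (-0.15) did not pass.

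**Figure D3:**
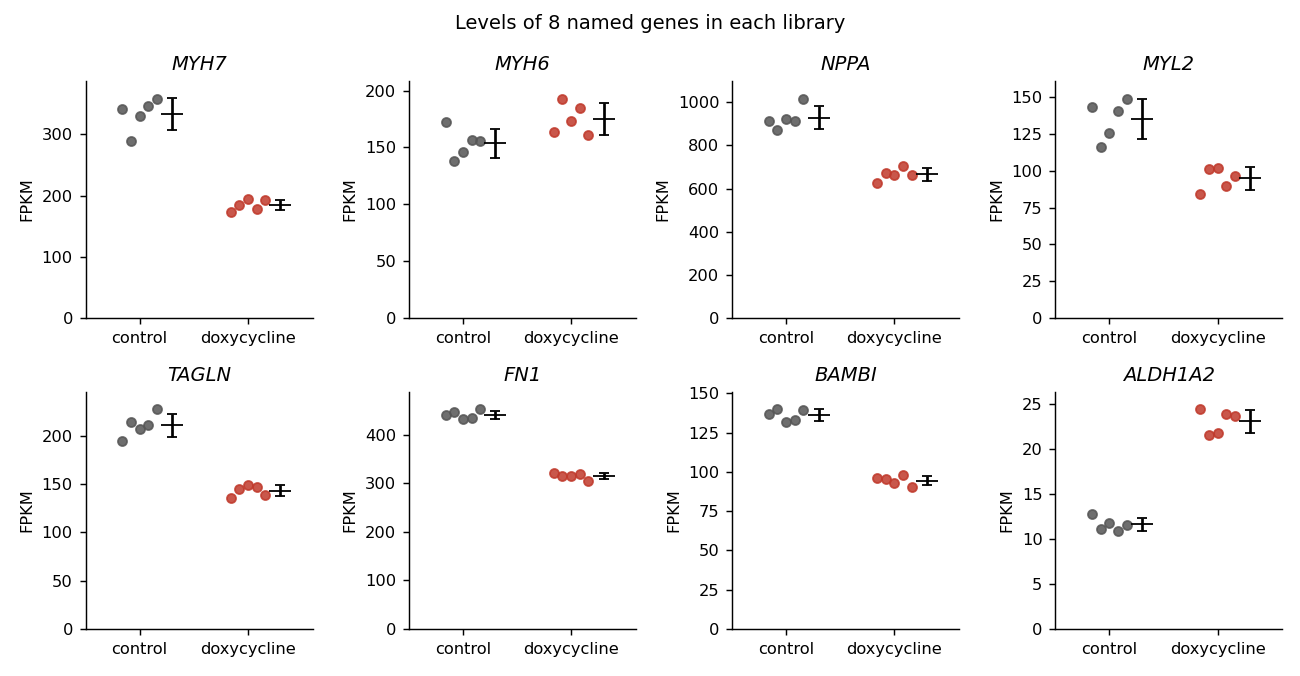
FPKM (vertical axes, from 0) of MYH7, MYH6, NPPA, MYL2, TAGLN, FN1, BAMBI and ALDH1A2 in each control and doxycycline library (points), with the mean and SD of each group beside them. MYH7 fell from 333.1 to 184.6 FPKM and ALDH1A2 rose from 11.6 to 23.1, without overlap, while the MYH6 libraries overlap.

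The list of pathological hypertrophy genes, the fetal programme that failing or overloaded heart muscle switches on, fell in 9 of 19 members with none rising (13 adjusted over the list alone, camera adjusted p = 8.18e-12, and adjusted p = 0.00134 with an estimated correlation). Besides MYH7 these included NPPA, atrial natriuretic peptide, which went from 927.1 ± 53.3 to 665.8 ± 28.6 FPKM (SD, n = 5 each; adjusted p = 7.63e-06), the stretch-responsive ANKRD1 (-0.58) and CCN2, a matricellular protein (-0.51). NPPB, B-type natriuretic peptide, did not pass (-0.21, adjusted p = 0.0659). MYH7 is also in the sarcomere and ventricular lists, and NPPA in the atrial and nodal list. What the fall of this list says about the state of the cells was not tested. The list of physiological growth genes, which holds CITED4 itself, had 1 member that rose and 3 that fell among 27, and 5 and 6 adjusted over the list alone (camera adjusted p = 0.491). CITED4 was the member that rose, and those that fell were its paralog CITED2 (-0.32) and the insulin receptor substrates IRS1 (-0.28) and IRS2 (-0.29). The list's median was 0.02 and its mean 0.08, while camera's direction was lower and fry's higher (fry adjusted p = 0.0392). The higher mean and fry's direction rested on CITED4: without it, a setting chosen after the data were seen, the mean of the other 26 members was -0.03 and both directions were lower. CEBPB, a growth-related transcription factor, was at 18.9 ± 1.98 and 20.3 ± 1.68 FPKM (SD, n = 5 each; adjusted p = 0.459), and PPARGC1A at -0.16 on the log2 scale (adjusted p = 0.245).

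Smooth muscle, matrix and signalling genes fell beside them. In the smooth muscle list 8 of 12 fell (9 adjusted over the list alone, camera adjusted p = 1.72e-12), with TAGLN at -0.56, ACTA2 at -0.42 and LMOD1 at -0.31 on the log2 scale. In the fibroblast and extracellular matrix list 11 of 26 fell and 1 rose (14 and 1 adjusted over the list alone, camera adjusted p = 8.64e-10). Fibronectin, FN1, went from 441.1 ± 8.37 to 314.8 ± 6.14 FPKM (SD, n = 5 each; adjusted p = 2.08e-07), tenascin TNC fell by 0.51 and the crosslinking enzyme LOX by 0.54, while FBLN2 rose by 0.56. Of 19 targets and members of TGF-beta and BMP signalling 10 fell (12 adjusted over the list alone, camera adjusted p = 1.07e-11), with TGFBI at -0.67, the receptor-like BAMBI at -0.52, BMP4 at -0.46 and ID4 at -0.28. In the Wnt and Notch list 3 of 12 fell (6 adjusted over the list alone, camera adjusted p = 2.52e-05). They were DKK1 (-0.50), JAG1 (-0.34) and AXIN2 (-0.23), and HES1 did not pass (-0.19). The call of AXIN2 ended with the replicate block (adjusted p = 0.0717) and without control 1, 3 or 4 or doxycycline 2, 3, 4 or 5 (adjusted p up to 0.083). Of 14 immediate early genes 5 fell (6 and 1 higher adjusted over the list alone, camera adjusted p = 2.78e-05), with IER3 at -0.52, KLF6 at -0.45, DUSP1 at -0.43 and JUN at -0.27.

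Markers of other cell types moved as well. In the endothelial and endocardial list 3 of 9 fell, with NPR3 at -0.54, SOX17 at -0.50 and CDH5 at -0.33 (3 adjusted over the list alone, camera adjusted p = 0.00604, and adjusted p = 0.0592 with an estimated correlation), and KDR did not pass (-0.15). In the endoderm and hepatic list 3 of 8 fell, SOX17, SERPINA1 (-0.44) and CDH1 (-0.19), with 4 adjusted over the list alone (camera adjusted p = 0.000874, and adjusted p = 0.0445 with an estimated correlation), while TTR did not pass (-0.20). In the epithelial list 4 of 11 fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.0176, and adjusted p = 0.136 with an estimated correlation), with KRT7 at -0.53, KRT18 at -0.16 and CLDN3 at 0.34. In the epicardial list 2 of 14 rose and 3 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.834). ALDH1A2 and UPK3B (0.25) rose, and SEMA3D (-0.54), KRT18 and KRT8 (-0.15) fell. The list's median and mean were both 0.04, while camera's direction was lower. Of 4 tested neural genes, too few for camera, TUBB3 (-0.61), NES (-0.43) and GAP43 (-0.25) fell and SYT1 did not pass (0.00), and 3 fell adjusted over the list alone. Of 3 tested skeletal muscle genes ACTA1 and CKM (-0.54) fell, with 2 adjusted over the list alone. KRT8 and CKM were chosen after their values were seen. With the replicate block CDH5, CDH1, SERPINA1, KRT18 and UPK3B did not pass (adjusted p = 0.0717, 0.0983, 0.0636, 0.0586 and 0.0756). Their calls also ended without single libraries: CDH5 without control 1, 2 or 5 or doxycycline 1, 4 or 5 (adjusted p up to 0.0998), CDH1 without any but control 4 and doxycycline 5 (up to 0.0993), and SERPINA1 without control 1 or doxycycline 1 (up to 0.0557). KRT18 lost its call without control 2, 3, 4 or 5 or doxycycline 1, 3 or 5 (adjusted p up to 0.0772), and UPK3B without control 1, 2 or 4 or doxycycline 1, 2 or 4 (up to 0.0783). Of 5 tested pluripotency genes none passed limma's threshold, 2 had an unadjusted p under 0.05 and 1 was lower adjusted over the list alone (camera adjusted p = 0.369).

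Metabolic genes shifted in both directions. Among 13 mitochondrially encoded transcripts 4 rose and 3 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.504). CYTB went from 3356 ± 129.3 to 4214 ± 146.7 FPKM (SD, n = 5 each; adjusted p = 3.93e-05) and ATP6 rose by 0.21 on the log2 scale, while COX1 fell by 0.14 and ND4L by 0.13. With no filter on low values 1 transcript, CYTB, rose and 0 fell by limma, with the same fold changes (ATP6 adjusted p = 0.104, COX1 0.423 and ND4L 0.12). Under quantile normalization CYTB was at 0.00 and ATP6 and ND4L no longer passed. Of 41 nuclear genes of oxidative phosphorylation NDUFB10 rose (0.19, adjusted p = 0.0408), 0 passed adjusted over the list alone, and the list passed as higher (camera adjusted p = 0.0461, and adjusted p = 0.408 with an estimated correlation). The list's call ended with median scaling (adjusted p = 0.102), with TPM (adjusted p = 0.0845), with the replicate block (adjusted p = 0.057) and without control 1, 3 or 4 or doxycycline 2 or 4 (adjusted p of 0.0725 to 0.18). That of NDUFB10 ended with the replicate block (adjusted p = 0.0911) and without control 1, 2 or 3 or doxycycline 1, 2 or 4 (adjusted p of 0.0696 to 0.0995). COX7C (0.08), SDHB (0.12) and NDUFB8 (0.12) did not pass. In fatty acid oxidation 1 of 26 rose and 4 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.975), with PDK4 at -0.37, LPL at -0.36, FABP3 at -0.21 and CPT2 at 0.17. The median of that list was 0.03 and its mean -0.01. CPT2 and FABP3 did not pass with the replicate block (adjusted p = 0.0996 and 0.0744), nor CPT2 without control 2 or 3 or doxycycline 2 or 4 (up to 0.065), nor FABP3 without control 3 or 4 or doxycycline 1 (up to 0.0606). In glycolysis 1 of 23 rose and 5 fell (3 and 7 adjusted over the list alone, camera adjusted p = 0.0317, and adjusted p = 0.311 with an estimated correlation). The call ended without control 5, doxycycline 1 or doxycycline 5 (adjusted p = 0.162, 0.0533 and 0.162). Its members included HK2 at -0.24, the glucose transporters SLC2A3 and SLC2A1 at -0.20 and -0.19, and ALDOC at 0.25. HK2 did not pass with the replicate block (adjusted p = 0.0522). Of 26 hypoxia targets 2 rose and 7 fell (4 and 10 adjusted over the list alone, camera adjusted p = 0.00132). P4HA2 rose by 0.27, and VEGFA did not pass (-0.06, adjusted p = 0.546). In cholesterol synthesis 2 of 25 rose, SREBF1 (0.28) and TM7SF2 (0.26), both chosen after their values were seen (2 adjusted over the list alone, camera adjusted p = 0.703). The median of that list was -0.01 and its mean 0.01, and camera's direction was lower.

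**Figure D4:**
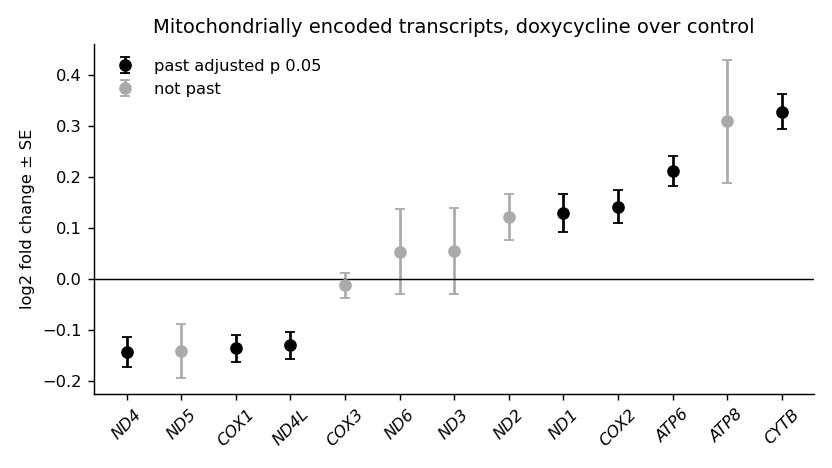
log2 fold change and its SE (vertical axis) of the 13 mitochondrially encoded transcripts (horizontal axis), in black where the adjusted p passed 0.05 and in grey where it did not. CYTB is highest at 0.33 and ND4 lowest at -0.14.

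In the calcium handling and ion channel list 2 of 21 rose and 4 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.0101, and adjusted p = 0.339 with an estimated correlation), with CASQ2, the calcium store protein, at -0.62 and JPH2 at -0.30. Of 35 cell cycle genes 0 passed limma's threshold, 4 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone (camera adjusted p = 0.785), and MKI67 was at 13.6 ± 0.52 and 13.04 ± 0.90 FPKM (SD, n = 5 each). Of 29 ribosome biogenesis genes 0 passed limma's threshold, 4 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone (camera adjusted p = 0.0536). Of 23 p53 targets 3 fell, CDKN1A (-0.18), PLK3 (-0.22) and TP53INP1 (-0.31), with 4 adjusted over the list alone (camera adjusted p = 0.00765, and adjusted p = 0.0445 with an estimated correlation), and TP53I3 did not pass (-0.14). With the replicate block PLK3 and TP53INP1 did not pass (adjusted p = 0.0761 and 0.0707), nor did PLK3 without control 2, 3 or 5 or doxycycline 1, 4 or 5 (adjusted p of 0.0501 to 0.0834), nor TP53INP1 without control 1, 2, 3 or 4 or doxycycline 1, 2 or 4 (adjusted p of 0.0535 to 0.0839). Of 29 ATF4 targets 2 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.483): TRIB3 (0.45) and ATF5 (0.24) rose, and VLDLR (-0.21) and STC2 (-0.25) fell. The call of STC2 ended without control 3 or 4 or doxycycline 1, 2 or 4 (adjusted p up to 0.0728). The median of that list was -0.02 and its mean 0.00. ASNS, an ATF4 target, was below the filter, at 0.38 ± 0.14 and 0.23 ± 0.05 FPKM (SD, n = 5 each). In the unfolded protein list 1 of 20 fell (camera adjusted p = 0.409), in the chaperone list 1 of 17 (camera adjusted p = 0.145) and in the autophagy and lysosome list 1 of 27 (camera adjusted p = 0.703), with 1, 1 and 0 lower adjusted over the list alone. The members that fell, chosen after their values were seen, were HERPUD1 (-0.14), CRYAB (-0.18) and BNIP3 (-0.18). The unfolded protein list had a median of 0.01 and a mean of -0.01, and the autophagy list a median of 0.01 with camera's direction lower. Both medians lay below the 0.022 of all tested genes. Of 13 interferon response genes 0 passed limma's threshold, 2 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone, yet the list passed as lower (camera adjusted p = 0.0214, and adjusted p = 0.615 with an estimated correlation). Without control 5 its adjusted p was 0.737, without doxycycline 3 0.0532 and without doxycycline 5 0.0984. IFI27 (-0.95), MX1 (-0.76) and IFIT3 (-0.52) did not pass, and control 5 held the highest MX1 level, 11.9 FPKM, of all libraries.

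**Figure D5:**
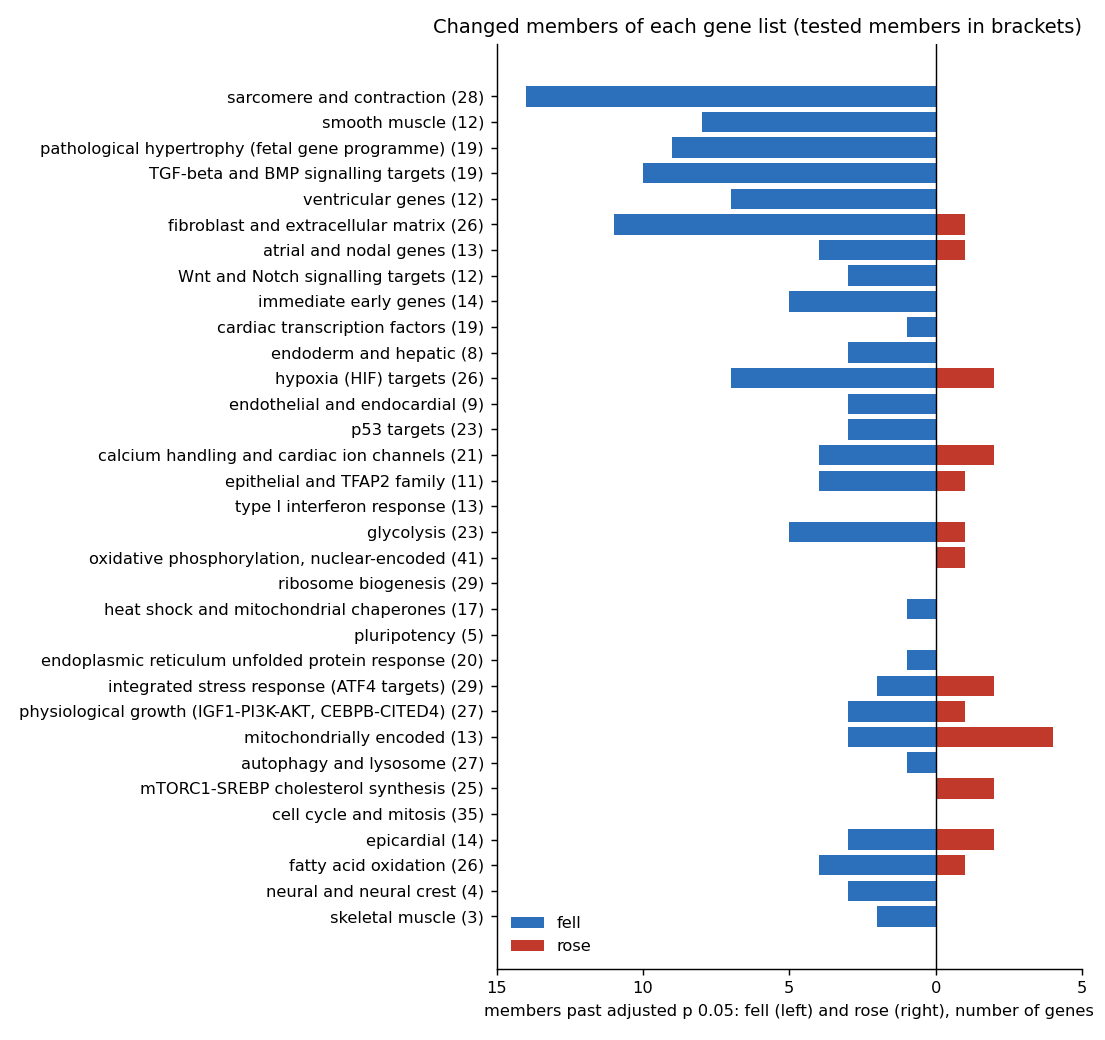
Number of members of each of the 33 lists (vertical axis, with the tested members in brackets) that fell (bars to the left) and rose (bars to the right) past the threshold. The sarcomere list has the most members that fell, 14, and the mitochondrially encoded list the most that rose, 4.

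In all, 19 of the 31 tested lists passed camera, 18 lower and 1 higher with doxycycline, and 12 still passed with an estimated correlation, each of them lower. Their adjusted p was then 0.00134 to 0.0445, much larger than with the preset correlation. Other groupings of the same libraries gave up to 21 lists with the preset correlation and at most 1 with the estimated one. Those that matched the real count exchanged 1 library between the groups, and so kept part of the real contrast. The median over the other groupings was 7 lists with the preset correlation and 0 with the estimated one. A grouping with 2 libraries exchanged, which kept less of the contrast, still gave 13 lists with the preset correlation and 0 changed genes. The small p-values with the preset correlation are therefore to be read with care. The lists share members, such as MYH7 in 3 of them, so they are not independent. Over all lists 119 members changed, 19 higher and 100 lower.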

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

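The tests of explanations in this part were chosen after the results were seen, and the check for outlying libraries before. Among 244 groups of 5 libraries checked, 1 library stood far from the other 4 in 9, where chance would give about 12.2. These were SMIM1 in control 2 (3.96 FPKM, others 6.96 to 7.74), GADD45G in doxycycline 5 (3.99, others 5.44 to 6.09), NPR3 in control 1 (3.91, others 2.93 to 3.03), SYT1 in control 5 (3.22, others 3.90 to 4.05), ANKRD1 in control 2 (431.5, others 341.5 to 357.8), IFIT3 in control 5 (4.29, others 0.95 to 1.43), MX1 in doxycycline 4 (3.33, others 0.76 to 1.04), DKK1 in control 4 (5.60, others 6.75 to 7.25) and the recovered depth of control 2 (35.2 M fragments, M standing for 1000000, others 39.3 to 39.6 M).

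The genes that rose were GC-rich, 229 of 531 lying in the upper GC range, and the libraries differed in how their values depended on GC content, with slopes from -0.08 to 0.09 log2 units per 10 points. Control 5, doxycycline 2 and doxycycline 4 had the steepest positive slopes. The main axis of spread within groups held 36.2% of that spread and followed gene GC content across genes (Spearman 0.81; genes are not independent replicates). GC-dependent yield as the whole cause of the rises is argued against by the correction for it, after which 473 of the 531 rises (89.1%) were still called. As the correction raised all calls from 1133 to 1700, a kept call can go with a smaller fold change. Without the 3 GC-rich libraries, with 7 libraries left, 255 of the 531 rises and 406 of the 602 falls were still called. After that correction 192 genes rose and 202 fell in the upper GC range, against 229 and 57 before, and 61 rose in the lower range against 14 before, so much of the skew moved with the GC trend. Its origin stays open: the mean slopes of the groups differed by 0.03 with an exact permutation p of 0.397, so yield and an effect of the treatment on GC-rich genes cannot be told apart here.

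Contractile, smooth muscle, matrix and TGF-beta genes fell together, 43 of 84 tested members of the 4 lists with 1 rising. GC-dependent yield as the whole cause is argued against, since 43 of the 43 were still called as lower after the GC correction. That correction raised all calls from 1133 to 1700, so kept calls do not show that the falls kept their size. A lower share of cardiomyocytes would lower smooth muscle and matrix genes only if cardiomyocytes expressed them more than the other cells, which was not tested. Outside the sarcomere list these genes had a median of -0.176 (95% bootstrap interval over genes -0.334 to -0.086, 37 genes), so for them this share stays open. The fold changes of the sarcomere genes had an SD of 0.243 (exact permutation p = 0.0079). That SD cannot decide, as a lower share would lower genes unequally where other cells express some of them. MYH6 rose adjusted over the list alone, but not past the main threshold (limma adjusted p = 0.0689). Markers of other cell types outside the 4 lists had a median of -0.083 (-0.17 to 0.003, 45 genes), and a lower share of cardiomyocytes stays open. A lower share of fibroblasts and smooth muscle cells would not lower sarcomere genes, whose median outside the smooth muscle list was -0.238 (-0.328 to -0.182, 27 genes). The fold changes of the matrix genes had an SD of 0.252 (exact permutation p = 0.0079), which likewise cannot decide. FBLN2 rose, which a lower share of these cells alone would not bring about if they are its source. A part played by a lower share of these cells stays open. Effects of CITED4 and of doxycycline itself stay open as well, and the design does not separate them.

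Mitochondrially encoded transcripts moved both ways. A change in their amount as a whole would move them alike, but the SD of their 13 log2 fold changes was 0.167, with an exact permutation p of 0.0079; with no filter on low values 1 of them rose and 0 fell past limma's threshold, at the same fold changes. GC content and length are argued against, since that SD was 0.166 after the correction for both. Doxycycline inhibits mitochondrial translation, and a response of ATF4 targets to that was looked for. Their adjusted camera p was 0.483, with a median of -0.02 (95% bootstrap interval -0.04 to 0.02), which does not exclude it, and without doxycycline-treated cells lacking the transgene the drug and CITED4 cannot be told apart. Reads shared with nuclear copies of mitochondrial genes were not tested.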

How the results depend on the processing

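The GC settings and the fit without GC-rich libraries were chosen after the data were seen. CITED4 kept its direction and call in each alternative, between 2.77 (pseudocount 5) and 3.13 (pseudocount 0.1), and between 3.01 and 3.09 with each library left out in turn. The main count of 1133 changed genes became 1700 (727 higher, 973 lower) with the GC correction, 1702 with the GC and length correction, 1802 (993 higher, 809 lower) with the GC slope as a covariate and 747 without the 3 GC-rich libraries, where fewer samples were used, and ran from 817 to 1255 with each library left out in turn; the cause of the rest was not tested. With the replicate number as a block it was 639. Correlations of same-numbered libraries ran from -0.464 to 0.175, and 1 of 10 libraries correlated best with its own number. The main axis of spread within groups, which followed GC content, enters these correlations. On it control 5 was at 0.559 and doxycycline 5 at -0.395. The correlations therefore cannot decide whether equal numbers mark paired libraries. Median scaling, TPM and quantile normalization lowered the share of higher calls from 46.9% to 38%, 39.7% and 38.3%. The 3 genes changed by 2-fold or more became 8 with a pseudocount of 0.1 and 1 with a pseudocount of 5. This is by construction, as a larger pseudocount shrinks low genes. The count was 5 with TPM and 7 with TPM without mitochondrial genes and CITED4. Summed FPKM was 362388 to 378394 and TPM sums to 1000000, so under TPM a pseudocount of 1 shrinks low genes less. Whether that was the whole cause was not tested. With the GC slope as a covariate the count was 6. It was 2 to 5 with each library left out in turn, with 5 without control 3. Lists past camera were 19, 17 to 19 with each library left out in turn, and 12 with an estimated correlation. Changed members were 119, and 98 to 121 with each library left out. Of 91 named genes past the threshold, 66 passed in each alternative run. Over all comparisons of named genes with an alternative, 2753 of 2969 kept direction and side of the threshold, 130 lost the call, 75 gained it and 11 changed sign. For lists these were 789 of 834 kept, 33 lost and 12 gained. Oxidative phosphorylation was the least stable list, past the threshold in 11 of 27 alternatives, and interferon response passed in 20 of 27, not without control 5, doxycycline 3 or doxycycline 5. Glycolysis passed in 22 of 27, not without control 5, doxycycline 1 or doxycycline 5. SYT1 log2 fold change, 0.0030 as reported, was -0.0124 with median scaling, -0.0121 with TPM, -0.0116 with quantile normalization, -0.0085 with TPM without mitochondrial genes and CITED4, -0.0012 with array weights and -0.0016 without the GC-rich libraries, and ran from -0.0435 to 0.0211 with each library left out in turn, below 0 without control 5, doxycycline 1 or doxycycline 3. TNNI3 log2 fold change and CEBPB log2 fold change were -0.0159 and -0.0091 after the GC and length correction; the cause was not tested. AXIN2, CDH1, CDH5, CPT2, FABP3, IRX4, KRT18, NDUFB10, PLK3, SERPINA1, STC2, TP53INP1 and UPK3B lost their call without at least 1 library, with adjusted p up to 0.0998, and each of these but STC2, with HK2, also with the replicate block. With no filter on low values 19 named genes lost the call and without the GC-rich libraries 16. SMIM1 and MHENCR were among both, and ALDOC and IRS2 among the latter (limma adjusted p = 0.0576 and 0.0527). CYTB, ATP6 and ND4L lost their calls under quantile normalization, which by construction gives equal values to a gene of equal rank in each library; CYTB was at 0.00. An FPKM of 1 over 1 kb rests on 35.2 to 39.7 fragments, which limits short and low genes.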

Other observations

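The gene families, the retinoic acid and YAP/TEAD targets, the myosin share and the tests on them were chosen after the results were seen, and what the regroupings of the libraries would show was set down only after their result. All 6 actin genes tested fell, 4 of them members of the 33 lists, and of 8 keratins 4 fell and 1, KRT4, rose. The 13 families and lists with at least 5 tested members outside the 33 lists were tested on those members. With the preset correlation 4 passed, those below and YAP/TEAD targets, and 9 did not, collagens, protocadherins, semaphorins and antisense genes among them (camera adjusted p of 0.158 to 0.689). With an estimated correlation 0 passed. Of 16 integrin genes 7 fell and 0 rose (camera adjusted p = 5.89e-06, and adjusted p = 0.0624 with an estimated correlation). Of 11 tubulin genes 4 fell and 0 rose (camera adjusted p = 0.0175, and adjusted p = 0.589 with an estimated correlation). Cytosolic ribosomal protein genes passed as higher with 3 of 81 members rising (camera adjusted p = 0.000264), and did not pass with an estimated correlation (adjusted p = 0.589). With all tested members, those in the 33 lists included, these families kept their directions with median scaling, TPM, quantile normalization and TPM without mitochondrial genes and CITED4. The ribosomal protein genes that rose numbered 1 with median scaling or TPM, 2 with TPM without mitochondrial genes and CITED4, and 5 with quantile normalization.

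The share of MYH6 in the cardiac myosin heavy chains was computed after the fall of MYH7 had been seen and largely restates it, as MYH6 itself did not pass (limma adjusted p = 0.0689). MYH6 made up 48.6% ± 2.43 (SD, n = 5) of summed MYH6 and MYH7 FPKM with doxycycline and 31.6% ± 1.32 (SD, n = 5) in control libraries, a difference of 17.1 points (exact permutation p = 0.0079), which stayed between 16.5 and 17.9 with each library left out in turn. The genes are neighbours on chromosome 14, from 23381990 to 23408277 and from 23412738 to 23435718 on GRCh38 (GENCODE 29) and have similar sequences, and how reads that match both were assigned was not tested. The ratio of MHRT to MYH7 did not differ past the threshold (difference -0.26 on the log2 scale, exact permutation p = 0.238).

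Interferon response genes varied within groups. The mean log2(FPKM + 1) of 13 of them was 3.91 in control 5, 3.26 in doxycycline 4 and 3.22 in control 2, and from 2.60 to 2.99 in the other 7 libraries. The within-group SD of MX1 was 0.85 on the log2 scale, against a median of 0.10 over 11962 genes.

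ALDH1A2 rose, and higher retinoic acid signalling was tested as a hypothesis. Of 15 retinoic acid targets HOXB2 and CRABP2 rose, the median was 0.02 (95% bootstrap interval -0.08 to 0.16), and the list did not pass (camera adjusted p = 0.721), which leaves the hypothesis open.

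YAP/TEAD targets fell in 8 of 20 members (camera adjusted p = 2.93e-08, and adjusted p = 0.0295 with an estimated correlation), CCN2 and ANKRD1 among them. Because the list was chosen after falls of such genes had been seen, its 16 members in none of the 33 lists were tested apart: 4 fell and 0 rose, with a median of -0.09 (95% bootstrap interval -0.16 to -0.002), a camera p of 6.1e-05 and a p of 0.00961 with an estimated correlation, which adjusted over the families and lists chosen after the data became an adjusted p of 0.0624. Lower YAP/TEAD activity may accompany the treatment, as a hypothesis found and tested on the same data.

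Whether chance could give the counts was asked with 100 of the groupings of the 10 libraries into 5 and 5, the real one included. For changed genes, 1 of the 100 gave as many, the real one with 1133 against at most 1 in the others, and for 2-fold changes 1 of 100, with 3 against at most 1. For changed list members it was 1 of 100, with 119 against at most 0. Under chance alone the real grouping would rank first in about 1 of 100 draws, which for these counts argues against chance without excluding it. The other groupings mix treated and control libraries, so a real difference adds to their spread and lowers their counts. A difference in culture or handling between the groups would look the same. For the number of lists past camera with the preset correlation, 5 of 100 groupings gave as many, with 19 in the real one and up to 21 in the others. Each of those 4 exchanged 1 library between the groups and so kept part of the real contrast. The median over the other groupings was 7 lists, and 1 with 2 libraries exchanged gave 13. The comparison therefore cannot decide whether chance could give that number. With the estimated correlation 1 of 100 gave as many, the real one with 12 against at most 1. This argues against chance within the same limits.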
